A study of Mus musculus with 6 samples.

How the data were processed

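Liver RNA of male C57BL/6J mice was measured on 6 one-colour Affymetrix mouse 3' expression arrays. The control group drank distilled water and the other group drank source water, for 90 d. Per the labels, each group held 10 mice, the livers of 9 were used, and the livers of every 3 mice were homogenised together, which gave 3 RNA pools and 3 arrays per group. Each replicate is therefore a pool of 3 mice, and its spread is smaller than that between single animals. The animals' pooling order and the hour of collection were not given in the sources used here.

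The deposited values are log2 signals per probe set, 1 column per array, and the submitters' processing notes name RMA and Partek without versions. Their background correction and normalization settings were not given in the sources used here. The authors also deposited a table of their comparison, which holds a p-value, a ratio and a signed fold change per probe set, and the test behind the deposited p-values was not given in the sources used here. An ordinary 2-group test on the deposited log2 values did not return the authors' p-values (Spearman correlation 0.939 across probe sets, which are not independent replicates), while the authors' group means differed from those of the value table by at most 7.7e-05. The authors' p-values and fold changes are described as theirs and enter no other test. Array files carry no read depth, so precision is limited by the number of arrays. Probe sets near the background floor understate differences.

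Of 22690 probe sets, 64 control probe sets were left out, and 22626 were tested. Gene symbols came from the platform annotation and were looked up through Entrez identifiers in a gene table of assembly GRCm38.p6, which was used for names only. It matched 20351 probe sets and changed 0 symbols. A single symbol was given for 20380 probe sets, several for 691 and none for 1555. No gene was named from a probe set with several symbols. The 12393 genes were each represented by the probe set with the highest mean log2 value over the 6 arrays, and 4956 genes had more than 1 probe set.

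Source water was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no covariate), with Benjamini-Hochberg adjustment over all probe sets and an adjusted p threshold of 0.05. Each difference is a log2 difference, source water minus control, with the moderated standard error. A rule of unadjusted p under 0.05 with a fold change of at least 1.5 was also counted. On simulated data with 200 of the 22626 probe sets changed, the limma fit for this comparison recovered 0.5% of 1.5-fold, 91% of 2-fold and 100% of 4-fold changes, with 0, 11 and 9 false calls. The fit thus had little power for 1.5-fold changes. The simulated noise was independent between probe sets and used the moderated variances, so the shares for larger changes may not carry over to the data. There, Cyp2c55 at 5.69-fold and Vnn1 at 6.62-fold did not pass (limma adjusted p 0.137 and 0.373).

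The groups, tests, alternatives, 38 gene lists and the rule for named genes were fixed before the data were examined. Lists of liver pathways and of cell type markers were tested with camera, with a preset correlation between genes of 0.01 and adjustment over the 38 lists. Camera with an estimated correlation and fry were run beside it. The fry mixed test asks whether the genes of a list changed in either direction and does not compare the list with other genes. For each list, members were also counted with p-values adjusted over the list alone. In simulated data for this comparison, with 12393 genes, 2 of 2 lists shifted by 0.3 were recovered and 0 others were called, but that simulation held no correlation between genes. Named genes were, in each direction, up to 12 genes with the largest changes among those past the adjusted threshold, with groups that did not overlap and a mean above the median of all probe sets. Where fewer qualified, the genes of smallest unadjusted p with a 1.5-fold difference and the same filters filled the 12. From each list, up to 4 members past the test over the list alone were named, or else up to 2 members of smallest p.

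The alternatives were a block for the replicate number, a repeated quantile normalization, centring on array medians, 2 filters on dim probe sets, limma-trend, an unmoderated statistic, the mean of a gene's probe sets, and leaving out each array in turn. No slide or scan date was used here.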

Results

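Hepatic gene expression was compared between mice given source water for 90 d and control mice given distilled water, a comparison made to profile the transcriptional effect of the water. Each group had 3 arrays, each hybridised with RNA pooled from 3 mice. Array medians lay between 5.79 and 5.86 on the log2 scale, and arrays correlated pairwise at 0.9854 to 0.9935 across probe sets, which are not independent replicates. The first principal component held 36.5% of the variance and did not separate the groups, whereas the second, with 23.5%, placed all control arrays on one side and all source water arrays on the other.

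Elovl3, a fatty acid elongase, rose the most among genes past the test, from 8.98 ± 0.32 in control to 11.04 ± 0.41 in source water (log2 signal, mean ± SD, n = 3 per group), a 4.17-fold increase. Cyp2b10, a cytochrome P450 known as a target of the nuclear receptor CAR, rose 2.56-fold, and Peg3, an imprinted zinc finger gene, rose 3.13-fold. Nat8f5, a member of an N-acetyltransferase family, fell by 1.43 on the log2 scale. For these 4 genes, every source water array lay outside the range of the control arrays. The limma adjusted p-values were 0.0448 for Elovl3, 0.0124 for Cyp2b10, 0.00871 for Peg3 and 0.0278 for Nat8f5. All 3 probe sets of Cyp2b10 rose, by 1.36 to 1.54 on the log2 scale, although those that may also bind related Cyp2b transcripts cannot be assigned to Cyp2b10 alone. The other probe sets of Peg3 differed by 0.73 and 0.05, and the mean of its probe sets by 0.81. The adjusted p of Elovl3 was 0.0526 among probe sets above the median level, 0.0506 among those with a mean of at least 6, and 0.0589 with arrays centred on their medians. When each of the 6 arrays was left out in turn, Elovl3 passed in 1 run (adjusted p 0.0338 to 0.196), Nat8f5 in 1 (0.0336 to 0.12), Cyp2b10 in 3 (0.0279 to 0.114) and Peg3 in 4 (0.0243 to 0.0663), and the unmoderated statistic gave 0.294 to 0.496 for the 4 genes. The log2 differences in those 6 runs stayed at 1.862 to 2.268 for Elovl3, -1.519 to -1.29 for Nat8f5, 1.265 to 1.416 for Cyp2b10 and 1.553 to 1.749 for Peg3.

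In all, 9 of 22626 probe sets passed the limma test, 8 higher and 1 lower. Besides those of Elovl3, Peg3, Cyp2b10 and Nat8f5, they were a probe set of Ndrg1 (1.62), a probe set of Ncald (0.90), and one that carries several gene symbols. Without adjustment, 1362 probe sets (6.02%) had a p under 0.05. Of these, 337 also differed by at least 1.5-fold, 203 higher and 134 lower. Groups did not overlap for 10.7% of probe sets, where chance gives 10%. The count of 9 varied with the array left out, and each such fit held fewer arrays. It was 0 without control replicate 1, 14 without control replicate 2, 2 without control replicate 3, 1 without source water replicate 1, and 9 without source water replicate 2 or 3. At the gene level the count of 4 became 0, 7, 1, 1, 5 and 4 in the same order, of which 0, 3, 1, 0, 3 and 2 were among the original 4, and the gene called without source water replicate 1 was Cyp2c65. The unmoderated statistic called 0 probe sets after adjustment and 1249 without it.

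**Figure D1:**
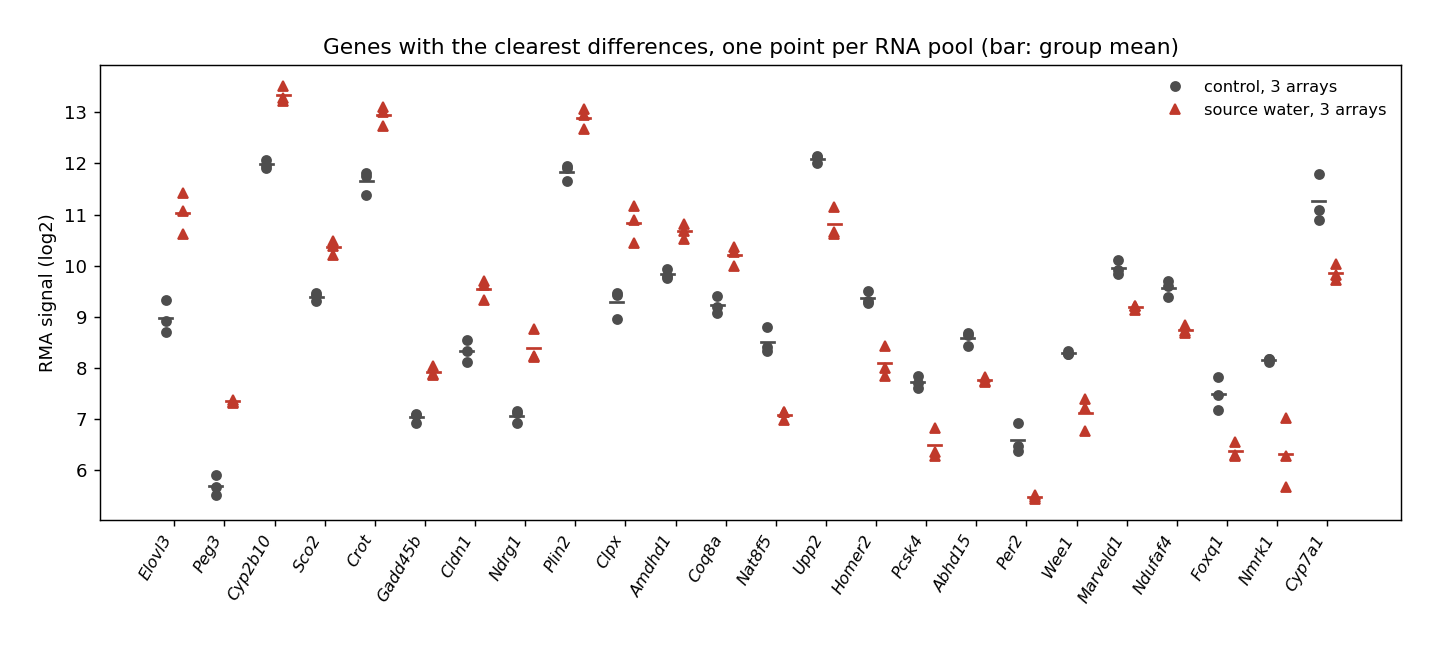
RMA signal (log2) of the genes named by the fixed rule, with 1 point per RNA pool, circles for control, triangles for source water and bars for group means. The groups do not overlap for any gene shown, and Elovl3 moves from 8.98 to 11.04.

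Further genes separated the groups without passing the adjusted threshold by their representative probe set, although another probe set of Ndrg1 passed it. On the higher side were Clpx, a mitochondrial protease subunit (log2 difference 1.56 ± 0.21, SE), Ndrg1 (1.34 ± 0.17), the carnitine acyltransferase Crot (1.30 ± 0.16), the tight junction gene Cldn1 (1.22 ± 0.15), and the lipid droplet gene Plin2 (1.06 ± 0.14). Coq8a (0.99), Sco2 (0.97), Gadd45b (0.89) and Amdhd1 (0.84) were also higher. On the lower side were Nmrk1 (-1.84 ± 0.29), Cyp7a1 (-1.41 ± 0.22), Upp2 (-1.29 ± 0.15), Homer2 (-1.28 ± 0.16), Pcsk4 (-1.23 ± 0.16), the cell cycle kinase Wee1 (-1.17 ± 0.16), Per2 (-1.12 ± 0.15) and Foxq1 (-1.12 ± 0.17). Abhd15 (-0.83), Ndufaf4 (-0.81) and Marveld1 (-0.78) completed the group. Their limma adjusted p-values ran from 0.0516 to 0.0972. A second probe set of Nmrk1 differed by 0.06, and the mean over a gene's probe sets was smaller for Nmrk1 (-0.89), Cldn1 (0.56), Wee1 (-0.75), Per2 (-0.65) and Marveld1 (-0.49). Other probe sets of Ndrg1 differed by 0.11 to 1.62, and those of Gadd45b by 0.11 and 1.17.

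Targets of the xenobiotic receptors CAR and PXR were mostly higher in source water. Of 27 measured, 18 were higher and 9 lower, 5 rose when adjusted over the list alone, and 1, Cyp2b10, passed over all genes. Cyp2c55 rose by 2.51 ± 0.45 (log2, SE), Cyp2c65 by 1.96 ± 0.25 and Gadd45b by 0.89 ± 0.11. The control mean of Cyp2c65 was 4.06, near the floor, so its rise may be understated. The camera test gave an adjusted p of 0.00108, and the list had an adjusted p = 0.904 with an estimated correlation. The fry mixed test gave an adjusted p of 0.00126. Of 9 targets of the aryl hydrocarbon receptor, 0 passed when adjusted over the list alone, and Cyp1a1 differed by 0.64 ± 0.19 (camera adjusted p = 0.298). The NRF2 list had 1 of 28 members past the test over the list alone, Gstm4, which rose by 0.83 ± 0.14 (camera adjusted p = 0.757, and 0.0351 without source water replicate 1).

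Targets of PPAR-alpha, the receptor that governs hepatic fatty acid oxidation, were higher for 36 of 42 members. When adjusted over the list alone 4 rose, among them Vnn1 by 2.73 ± 0.68 (log2, SE), Plin2 by 1.06 ± 0.14, Fabp2 by 0.63 ± 0.15 and Gpd1 by 0.53 ± 0.11, and 0 passed over all genes. The mean log2 difference was 0.317 (camera adjusted p = 4.69e-07), with an adjusted p = 0.692 with an estimated correlation. Without control replicate 2 the mean was 0.176 (camera adjusted p = 0.00244, and adjusted p = 0.836 with an estimated correlation). Vnn1 then differed by 1.77 and passed over all probe sets (limma adjusted p = 0.0243, against 0.373 with all arrays). With all arrays, the mean of the probe sets of Gpd1 differed by 0.26.

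Genes of lipid and bile acid metabolism moved in both directions. Of 27 genes of fatty acid and triglyceride synthesis, 5 passed when adjusted over the list alone and 0 over all genes. The lipogenic regulator Srebf1 fell by 1.23 on the log2 scale, Thrsp by 0.93 and Mid1ip1 by 0.76, whereas the elongase Elovl5 rose by 0.89 ± 0.21 (SE). Of 23 bile acid genes, 7 passed over the list alone, 4 higher and 3 lower, and 0 over all genes. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.41 and the sterol transporter Abcg5 by 0.72, while Nr0b2, a nuclear receptor that represses Cyp7a1, rose by 0.71 ± 0.11 and the phospholipid transporter Abcb4 by 0.64 ± 0.17. The fry mixed test gave adjusted p-values of 0.0492 for the synthesis list and 0.000208 for the bile acid list, while camera, which asks for a shift in 1 direction, gave 0.381 and 0.639. Without source water replicate 3 camera gave 0.0268 for the synthesis list, and without source water replicate 1 Thrsp differed by -0.61. Of 20 genes of cholesterol synthesis, 6 were higher and 14 lower, and 0 passed over the list alone (camera adjusted p = 0.188). That p was 0.0113 without control replicate 3 and 0.00229 without source water replicate 3.

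Genes of the unfolded protein response and of ATF4 were higher for 22 of 27 members. When adjusted over the list alone 8 rose and 1 fell, and 0 passed over all genes. The endoplasmic reticulum genes Creld2 and Manf rose by 1.19 ± 0.23 and 0.87 ± 0.17 (log2, SE), and Trib3 and Atf5 by 1.22 ± 0.31 and 1.10 ± 0.30. Camera gave an adjusted p of 8.3e-05, with an adjusted p = 0.692 with an estimated correlation, and the fry mixed test gave 0.0152. Heat shock genes were higher for 19 of 21 members, with 0 past the test adjusted over the list alone, and Hspb1 differed by 1.08 ± 0.38. Their camera adjusted p was 0.00101, with an adjusted p = 0.904 with an estimated correlation, and it was 0.261 without control replicate 2 (mean log2 difference 0.131 against 0.293) and 0.187 without source water replicate 3 (0.181). Without control replicate 3 the mean was 0.451.

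Of 18 clock genes and direct outputs, 11 passed the test adjusted over the list alone, 8 lower and 3 higher, and 0 passed over all genes. Usp2 fell by 1.46 on the log2 scale, Per3 by 1.22 and Per2 by 1.12, while Arntl, which encodes the activator BMAL1, rose by 0.98 ± 0.21 (SE). The other probe sets of Per3 differed by 0.09 and 0.03, and with the mean of each gene's probe sets Per3 differed by -0.37, Per2 by -0.65 and the list by -0.188 in place of -0.298 (camera adjusted p = 0.00218). The camera adjusted p was 0.000255, with an adjusted p = 0.692 with an estimated correlation, and the fry mixed test gave 0.00329. The labels give the light cycle and no hour of collection.

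**Figure D2:**
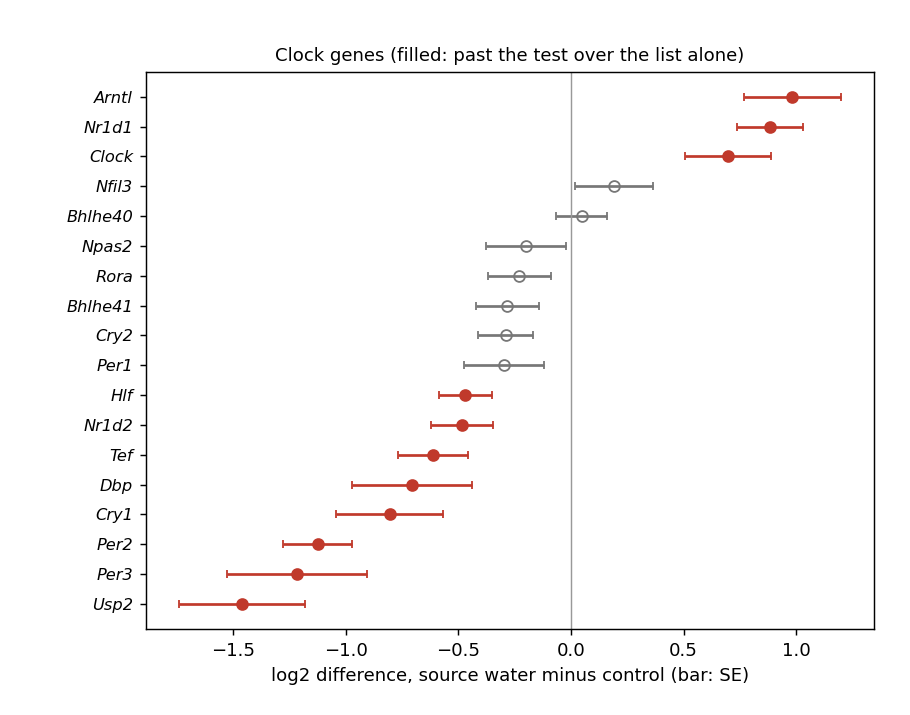
Log2 difference, source water minus control, of each measured clock gene with its SE, filled where the gene passed the test adjusted over the list alone. Usp2 lies lowest at -1.46 and Arntl highest at 0.98.

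Amino acid breakdown and urea cycle genes were lower for 22 of 31 members, and 1, the proline dehydrogenase gene Prodh, fell by 0.73 when adjusted over the list alone, with 0 past the test over all genes (camera adjusted p = 0.00921). The list had an adjusted p = 0.692 with an estimated correlation, and camera gave 0.0531 without control replicate 1 and 0.287 without source water replicate 2, where the mean moved from -0.137 to -0.065. Respiratory chain genes were lower for 43 of 57 members by a mean of -0.057, with 0 past the test adjusted over the list alone (camera adjusted p = 0.0186), and an adjusted p = 0.904 with an estimated correlation. That call ended without control replicate 1 (0.179), control replicate 3 (0.132) or source water replicate 1 (0.184). Metallothioneins and metal handling genes were lower for 13 of 16 members, with 0 past the test over the list alone. Mt1 differed by -0.59 ± 0.21 (camera adjusted p = 0.0273, and adjusted p = 0.692 with an estimated correlation). The call ended without control replicate 1 (0.0756), control replicate 2 (0.0563) or source water replicate 2 (0.063), and with the mean of a gene's probe sets (0.0768). Mt1 differed by -0.34 without source water replicate 2 and by -0.25 as the mean of its probe sets.

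Of 19 stellate cell and matrix markers, 13 were higher, and the collagen genes Col3a1 and Col1a2 rose by 1.33 ± 0.27 and 0.50 ± 0.13 when adjusted over the list alone, with 0 past the test over all genes (camera adjusted p = 0.0114). The list had an adjusted p = 0.692 with an estimated correlation, and second probe sets of Col3a1 and Col1a2 differed by 0.00 and 0.16, which made the means of their probe sets 0.67 and 0.33. Without control replicate 2 camera gave 0.0563. Interferon-induced genes were higher for 24 of 30 members, and Lgals3bp alone rose over the list, by 0.55 ± 0.11 (camera adjusted p = 0.000665, and adjusted p = 0.904 with an estimated correlation). Kupffer cell and macrophage markers were higher for 13 of 17 members, with 0 past the test over the list alone (camera adjusted p = 0.0411, and adjusted p = 0.904 with an estimated correlation). The interferon and macrophage lists lay at 0.433 and 0.418 above the mean of all arrays in control replicate 3 and at 0.452 and 0.211 in source water replicate 2. Both calls ended without control replicate 1 (0.207 and 0.409) or control replicate 2 (0.0639 and 0.835). The interferon mean of 0.287 ranged from 0.111 without control replicate 1 to 0.575 without control replicate 3, and the macrophage mean of 0.162 from 0.024 without control replicate 2 to 0.412 without control replicate 3. The macrophage call also ended without source water replicate 2 (0.394) or 3 (0.236), and under other normalizations and filters (0.0637 to 0.179).

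**Figure D3:**
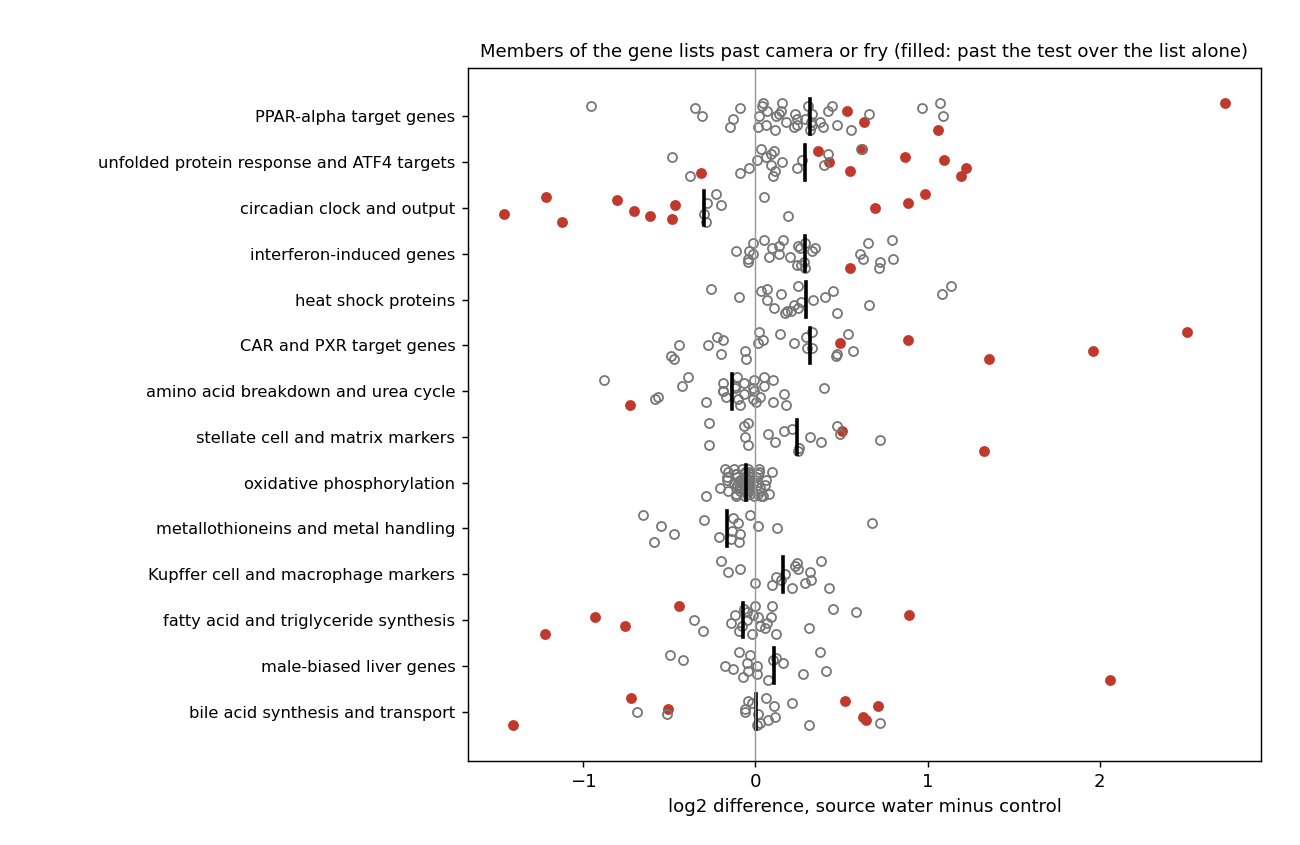
Log2 difference, source water minus control, of every member of the lists past camera or the fry mixed test, with list means as bars and filled points for members past the test adjusted over the list alone. PPAR-alpha targets have a mean of 0.317 and clock genes one of -0.298.

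Among the 38 lists, 11 passed camera, 7 higher and 4 lower, 0 did so with an estimated correlation or by the directional fry test, and 7 passed the fry mixed test. Of the lists past camera, those of CAR and PXR targets, the unfolded protein response, clock genes and amino acid breakdown also passed the fry mixed test. PPAR-alpha targets (adjusted p 0.054), stellate markers (0.0683), metal handling (0.276) and heat shock genes (0.485) did not pass the fry mixed test. Neither did the interferon list (0.539), respiratory chain genes (0.539) or macrophage markers (0.827). With the preset correlation, splits of the arrays that mixed the groups also gave 3 to 11 lists past camera. Single members passed over the list alone in 4 other lists: Elovl3 among male-biased genes, Fmo2 (fell by 0.86) among female-biased genes, Tk1 (fell by 0.85) among cell cycle genes, and Klf1 (fell by 0.61) among erythroid markers. Camera gave 0.609 for the male-biased list, and 0.0437 without control replicate 1, while the fry mixed test with all arrays gave an adjusted p of 0.00913. Lists of p53 targets (0.00153, mean 0.240 against 0.145) and acute phase genes (0.0334) passed camera without source water replicate 2, and cell cycle genes without source water replicate 1 (0.0351). Ribosomal proteins passed without control replicate 2 (0.029) or source water replicate 3 (0.0193). Markers of hepatocytes, of pericentral and periportal cells, and of endothelial, bile duct, T and NK, B, neutrophil, adipose, acinar and muscle cells had 0 members past the test over the list alone. The same held for antioxidant enzymes, conjugating enzymes, acute phase genes, p53 targets, glucose metabolism, ribosomal proteins and the proteasome.

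In the authors' deposited table, 1541 probe sets had a p-value under 0.05, of which 298 had a fold change of at least 1.5, 172 higher and 126 lower. Of the 337 probe sets past the same thresholds with limma, 292 were shared with that table. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 70 probe sets remained under 0.05.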

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

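The spike-in comparison was chosen only after the values were seen. In control probe sets that entered no comparison, the bacterial dap RNA added before labelling had a 3' minus 5' signal of 2.01 ± 0.17 (log2, SD, n = 3) in source water and 1.41 ± 0.22 in control, and the thr RNA one of 3.38 ± 0.11 and 2.78 ± 0.22. Both were singled out because every source water array lay above every control array, and the exact permutation p, two-sided, was 0.1 for each, the smallest that 3 arrays against 3 can give. The lys and phe RNAs differed by -0.04 and 0.05, and the mouse Actb and Gapdh control probe sets by -0.01 and -0.06.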

How the results depend on the processing

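All alternatives were planned. The calls depended on the variance model and changed when single arrays were left out. Against 9 probe sets and 4 genes, a repeated quantile normalization called 30 and 19, limma-trend 35 and 25, and the unmoderated statistic 0 and 0, and the mean of a gene's probe sets called 18 genes. The unmoderated statistic gave 213 probe sets past the 1.5-fold rule, against 337. Cyp2b10, Elovl3, Nat8f5 and Peg3 were all among the genes called in each of these except the unmoderated statistic. With the replicate number as a replicate block, 45 probe sets and 30 genes were called and the lists stayed at 11. Same-numbered arrays deviated together at -0.07, 0.28 and 0.17, and control replicate 1 correlated best with source water replicate 3 (0.43). For control replicates 2 and 3, the same-numbered source water array correlated best, at 0.28 against 0.27 and 0.17 against 0.05 for the next. These values do not settle whether same-numbered arrays share a batch. Leaving out 1 array gave 0 to 14 probe sets, 0 to 7 genes, 345 to 465 probe sets past the 1.5-fold rule and 7 to 12 lists. The CAR and PXR, PPAR-alpha, unfolded protein response and clock lists passed camera in each of these 6 runs. Lists fell from 11 to 0 with an estimated correlation and to 0 with fry. Among named genes and single lists, 1740 comparisons with an alternative kept the sign of the log2 difference and the side of the threshold, 66 kept the sign and lost the call, 72 kept it and gained one, and 43 changed sign. The changes of sign were all in means of lists that did not pass camera, and 1 of the 43 came with a call, acute phase genes without source water replicate 2 (0.149, adjusted p = 0.0334). The direction of the list test turned in 45 comparisons, of which 0 were called in either setting. The mean changed sign to -0.004 for bile acid genes after repeated quantile normalization, and to 0.008 for acute phase genes and 0.006 for hepatocyte markers with arrays centred on their medians. Among probe sets above the median level it moved to -0.004 for cell cycle and -0.026 for female-biased genes, and among those with a mean of at least 6 to -0.018 and -0.026. With the mean of a gene's probe sets it was -0.017 for bile acid genes and -0.009 for the proteasome. Leaving out 1 array gave ranges across 0 for genes of the acute phase (-0.091 to 0.149), bile acids (-0.038 to 0.047), cholesterol synthesis (-0.251 to 0.006), ribosomal proteins (-0.065 to 0.005), fatty acid synthesis (-0.166 to 0.013), glucose metabolism (-0.009 to 0.131), NRF2 targets (-0.040 to 0.154), the proteasome (-0.065 to 0.064) and conjugating enzymes (-0.158 to 0.042). The same held for female-biased (-0.065 to 0.170) and male-biased genes (-0.007 to 0.239), and for markers of hepatocytes (-0.032 to 0.014), periportal cells (-0.149 to 0.031), endothelium (-0.077 to 0.093), B cells (-0.001 to 0.143), T and NK cells (-0.057 to 0.104), neutrophils (-0.072 to 0.163), adipocytes (-0.024 to 0.031), acinar cells (-0.106 to 0.025) and muscle (-0.081 to 0.060). Apart from the smaller number of arrays when 1 was left out, the cause was not tested. Signal over background limits what dim probe sets can show.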

Other observations

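Apart from the splits of the arrays, the tests here were chosen only after the results they bear on were seen, and the genes named here outside the fixed rule were chosen after their values were seen. Cyp4a14, a PPAR-alpha target, read 11.05, 7.53 and 11.43 in the control pools and 13.2, 5.63 and 13.15 in the source water pools, so that 1 pool of each group stood far below the others. A probe set of Sephs2 read 9.92, 12.45 and 12.21 in control and 12.37, 12.43 and 9.42 in source water, and one of Rpl27a read 7.86, 10.18 and 10.3 against 10.17, 10.07 and 7.83. The same 2 arrays, control replicate 1 and source water replicate 3, had the lowest 18S ribosomal RNA signals, 13.12 and 12.35. A probe set of Nampt, an enzyme of NAD synthesis, had a log2 difference of -0.79 (limma adjusted p = 0.23). It was dim, at 5.24, 4.73 and 4.95 in control and 3.93, 4.3 and 4.34 in source water, below the array medians of 5.79 to 5.86.

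Of the 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05, the real one gave 9 probe sets and the highest other also 9. For genes the values were 4 and 5, for the 1.5-fold rule 337 and 395, and for the lists past camera 11 and 11, and in each case 2 splits, the real one included, reached the real value. Every other split also called lists by camera with the preset correlation, from 3 to 11 of them. A camera call alone is therefore not particular to source water. Lists past the fry mixed test numbered 7 for the real split and 8 for the highest other. The split with 395 set control replicates 1 and 3 and source water replicate 3 against the rest, was also the one with 8, and had 4020 probe sets at an unadjusted p under 0.05, against 1362 for the real split. This points to a structure of the arrays apart from the groups, technical or of the samples. The bacterial hybridisation control bioB read 7.3, 7.71 and 7.24 in those arrays, against 8.6, 7.93 and 8.36 in the rest. The first principal component also separated them. The source was not tested. The other split with 9 probe sets set control replicates 1 and 2 and source water replicate 1 against the rest, and its calls included H2-Ab1, H2-Aa, H2-Eb1, H2-DMa and Cd74, genes of antigen presentation.

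The clock genes may differ because the livers of the groups were collected at different hours. Of the 18 measured clock genes, the 16 with a textbook peak hour were used. A cosine of that hour explained 0.506 of the variance of their log2 changes, against a median of 0.1 for permuted hours (permutation p = 0.011, one-sided, 100000 permutations). The permutation treated the genes as independent, although genes with near peak hours may move together. Its p does not measure the spread between pools. The cosine was fitted to these same changes. Usp2 (-1.46 against a fitted -0.66), Nr1d1 (0.88 against 0.11), Per3 (-1.22 against -0.48) and Npas2 (-0.20 against 0.53) departed from it the most. A shift of the liver clock by the water, with livers collected at the same hour, predicts the same pattern and cannot be told apart, since 0 samples have a label that gives the hour of collection. Genes that cycle by the hour and are not in the clock list could share this source of difference, which was not tested.

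The higher PPAR-alpha targets could reflect a longer time since feeding in the source water mice. The mean log2 difference of 6 measured fasting-induced genes was -0.058 ± 0.384 (SE), with 2 of the 6 higher, a spread too wide to decide, and a seventh gene of the set, Sds, was not measured as a single gene. The set was written down before its genes were viewed one by one, but after the result of an overlapping list on glucose metabolism was known. A single deviating pool, control replicate 2, stays open as the source. The mean of the list was 0.317 with it and 0.176 ± 0.164 (SE over arrays) without it, and relative to the mean of all arrays the list lay at -0.054 and 0.019 in the other control pools, against 0.321, -0.088 and 0.243 in the source water pools. Without that pool the camera adjusted p was 0.00244 with the preset correlation and 0.836 with an estimated one, so the first alone does not exclude it. An effect of the water on the receptor stays open and was not tested separately.

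Probe sets of H2-K1, a histocompatibility gene, disagreed between pools: one read 12.02, 12.34 and 10.51 in control and 13.44, 8.53 and 12.64 in source water, another 10.87, 10.82 and 11.15 against 9.32, 11.82 and 11.1. The difference between the first 2, the pair that disagreed most, ranged over 7.42 log2 units, more than in 99.9% of 900 genes with at least 2 bright probe sets (median 0.41), which argues against a change in cell numbers alone, since that would move both alike. Alleles that differ between mice are a candidate explanation, as 2 of 5 H2 genes were among the 9 genes whose probe sets disagreed most (Fisher's exact test, one-sided, p = 0.000876). That test counts H2-K1, the gene that raised the question, so a second one without it was added after the first result was known: the other 4 H2 genes had a mean percentile of 89.7 (permutation p = 0.0012, one-sided), and H2-Ea among them had also been seen beforehand. The permutation treated the 4 genes as independent, but H2-Aa and H2-Ab1 were called together in another split, and H2-Aa ranged from 7.91 to 11.25. It therefore cannot tell alleles from such shared variation. Binding of other family members stays open. Of other H2 genes, 9 probe sets ranged at least 0.5 times as widely, but whether they rose and fell with H2-K1 was not tested. The labels name a single inbred strain.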
